A study of Oryza sativa with 4 samples.

How the data were processed

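Total RNA of the flag leaf collar of lc1 mutant and wild-type rice plants was measured on the Affymetrix Rice Genome array, with 2 arrays per genotype and biotin-labelled copy RNA as the target, per the labels. The deposited table holds 1 intensity per probe set and array on a linear scale, the MAS 5.0 signal, which per the series' design text came from the Affymetrix Microarray Suite, version 5.0. That text also names detection calls, a Wilcoxon change call of the same suite and a linear mixed model from the MAANOVA package as the authors' tests, and the submitters' processing notes name R 1.8.0. The detection calls and the probe-level data were not used here, so the change call was not run. Of 57381 probe sets, 123 Affymetrix controls were left out of the tests and 57258 were kept, the RPTR probe sets among them.

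The deposited signals had not been brought to one level across the 4 arrays: trimmed means (2% removed at each end) were 113.5 and 121.9 in the wild type and 159.7 and 126.7 in lc1. The design had assumed scaled signals and was kept as written, with median scaling and quantile normalization as alternatives. The median tested probe set lay 0.22 log2 units higher in lc1. Log2 differences and folds between the genotypes are given after subtracting that shift, while limma tested the difference as deposited against 0. Values from another setting subtract the shift of that setting. List medians on a single lc1 array, or in a split of the arrays other than by genotype, take each array relative to its own median probe set. No pair of arrays shared more than 1.64% of identical signals, so no array is a copy of another. That the arrays of a genotype are biological replicates rests on the labels.

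Signals were put on a log2 scale, with the 18 values of 0.0 set to 0.05. Probe sets whose mean log2 signal over all arrays was at or above the 40th percentile (2.58, a signal of 5.96) were tested, 34355 in all. The main test was limma 3.58.1 in R 4.3.3, with lmFit and eBayes with an intensity trend, genotype as the only term, 2 residual degrees of freedom, 2-sided, Benjamini-Hochberg adjustment and a threshold of 0.05. No p in the text comes from another kind of model unless named. As a measure of background, the floor of an array was the 95th percentile of its 23 Tag and TrpnX control probe sets, 9.02 and 11.9 in the wild type and 13.8 and 12.9 in lc1. Where both arrays of a genotype lay at or under the floor, a fold is given as a lower bound: the geometric mean of the brighter group over that of the dim group, with each dim array raised to its floor.

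Probe sets were named through the platform annotation supplied with the data and the gene table of assembly ASM3414082v1, which was used for names and neighbouring genes only. Of the 57258 probe sets, 22436 had 1 gene, 95 several and 34727 none, and all 22436 were found in the gene table. Among the tested probe sets were 16291 genes, of which 2264 had a name other than a locus number. For gene lists each gene was represented by its probe set with the highest mean signal. Probe sets of multigene families, including those with identifiers ending in _x_at or _s_at, can cross-hybridise between members.

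The 41 gene lists written before the data were examined selected genes by words in their descriptions, but the gene table holds no descriptions, and only 4 lists then had at least 5 measured genes. Of these 4, 3 were called (jasmonate with 15 genes, adjusted p = 0.00205; cellulose synthases, adjusted p = 0.0293; WRKY factors, adjusted p = 0.0400) and 0 with an estimated correlation. The lists used in the report select genes by patterns on symbols and synonyms. They were written after the gene table had been seen and before any signal was compared between the genotypes. There were 44, of which 42 had at least 5 measured genes and were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 42. Camera with an estimated correlation and fry, which tests the list against no change and not against other genes, were run beside it. Members were also adjusted over the list alone.

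The rule for named genes was fixed before the data were examined. It takes every measured GH3 gene, and, when fewer than 20 probe sets pass the threshold, the 10 higher and the 10 lower genes with the smallest p among those that differ at least 2-fold, whose genotypes do not overlap, whose brighter mean is at or above the median signal (13.2) and that have exactly 1 named gene. The rule also asked for an informative description, for which having a name other than a locus number stood in. GH3.9 was below the filter. The probe set past the threshold and list members named as examples were chosen after their values were seen.

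The test was checked on simulated data for this comparison, over 34355 probe sets with 200 changed in each of 10 simulations. With noise drawn from limma's fitted variance prior, 0.250% of probe sets changed 2-fold were called, 22.5% at 4-fold, 52.8% at 8-fold, 69.8% at 16-fold and 74.8% at 64-fold, with 50 of 341550 unchanged ones. With the spreads between the real replicates shuffled over probe sets, these shares were 0%, 0%, 0.250%, 8.25% and 24.8%, with 4 unchanged ones. Over 16291 simulated genes, camera called a list of 23 genes shifted by -0.70 in 10 of 10 simulations under either noise, and 0 of 420 unshifted lists. The simulated genes varied independently, so this check does not cover false calls from members that vary together, whose correlation was estimated at 0.359 for the Aux/IAA list and 0.755 for the jasmonate list.

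Alternatives fixed before the data were examined were the scalings above, no filter, a filter at the 60th percentile, a pseudocount of 2, a common variance prior, the replicate number as a block, leaving out each array in turn (where the lone array is assumed to vary like the other genotype), a gene-by-gene model without moderation, a count of 2-fold differences without overlap, leaving out probe sets that can cross-hybridise, the mean of each gene's probe sets, an estimated correlation and fry. A block that pairs the replicate numbers crosswise and fry on median-scaled signals were added after the data were seen.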

Results

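RNA from the flag leaf collar of rice, the lamina joint where the blade meets the sheath and where the leaf angle is set, was hybridised to the Affymetrix Rice Genome array. The lc1 mutant and the wild type were each measured on 2 arrays, 4 in all, and per the labels the arrays of a genotype are biological replicates. Each array carried 57381 probe sets. The median signal of the non-control probe sets was 11.8 and 12.1 on the wild-type arrays 1 and 2, and 16.1 and 13.0 on the lc1 arrays 1 and 2. The number of arrays limits the precision of every value. The ratio of 5' to 3' signal of the rice Gapdh control, a sign of RNA quality, was 0.164 and 0.236 in the wild type and 0.246 and 0.138 in lc1, so that it parted wild type 1 and lc1 mutant 2 from wild type 2 and lc1 mutant 1 and did not follow genotype. The median probe set lay 0.22 log2 units (1.17-fold) higher in lc1 as deposited, and differences between the genotypes are relative to that shift. In another setting they are relative to the shift of that setting. Medians on a single lc1 array instead take each array relative to its own median probe set. On that scale the median difference between the genotypes stayed at 0.07, so medians near 0 can differ in sign between the 2 scales. A log2 difference is given with its limma standard error (SE) over 2 arrays per genotype.

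The comparison asks which transcripts differ between the mutant and the wild type in the tissue that sets the leaf angle. GH3.1, an amido synthetase of the family that conjugates auxin to amino acids, was near background in the wild type and bright in lc1, at least 39.8-fold higher. The Aux/IAA genes, which code for repressors of auxin-responsive transcription, were lower in lc1 as a group, with a median 1.59-fold below the median probe set over 23 genes (camera adjusted p = 5.83e-16, and adjusted p = 0.937 with an estimated correlation). Jasmonate genes were higher as a group, by a median of 1.54-fold over 30 genes, mostly on lc1 mutant 1 (camera adjusted p = 0.00730, and adjusted p = 0.937 with an estimated correlation). A gene without a name in the annotation, LOC4347708, was 15.8-fold higher in lc1 and was the only probe set of 34355 to pass the test as deposited.

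LC1 is known from the literature as GH3.1, and the labels give neither the gene nor the kind of allele. The GH3.1 probe set had signals of 1.0 and 9.0 in the wild type, under the floor set by probe sets without a rice target on the same arrays (9.02 and 11.9), and of 551.8 and 418.1 in lc1. Both lc1 arrays stood above both wild-type arrays, and limma gave an adjusted p of 0.241 over all probe sets, which does not pass. The limma adjusted p was 0.0336 under median scaling of the same arrays, 0.0175 without wild type 2 and 0.0197 without lc1 mutant 2. It was 0.0832 under quantile normalization, 0.0657 without wild type 1 and 0.103 without lc1 mutant 1, which do not pass.

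The other members of the GH3 family went both ways. GH3.2 measured 666.5 ± 20.6 (SD, n = 2) in the wild type and 207.1 ± 96.9 (SD, n = 2) in lc1, a log2 difference of -1.99 ± 0.35. GH3.4 had signals of 18.5 and 24.1 in the wild type and lay under the floor on both lc1 arrays, at least 1.85-fold lower. GH3-8 gave a log2 difference of 0.94 ± 0.43 and GH3.6 one of 0.69 ± 0.34, with both lc1 arrays above both wild-type arrays in each case. GH3-8 gave 0.51 without lc1 mutant 1, and GH3.6 gave 0.36 without wild type 1 and 1.05 without wild type 2. GH3.7 (-0.35 ± 0.30) and GH3.5, also named JAR1 and known to conjugate jasmonate (-0.27 ± 0.32), differed by little more than their error or less, and GH3.11 was near the floor in both genotypes. Of the 8 tested GH3 genes, 5 passed limma when adjusted over the list alone. Of these 5, 3 were higher (GH3.1, GH3-8 and GH3.6) and 2 lower (GH3.2 and GH3.4). The list calls of GH3-8 and GH3.6 lay just under the threshold, in a test that kept the upward shift of the median probe set. Adjusted over the list, GH3.6 does not pass under median scaling, and neither gene passes under quantile normalization. Over all probe sets 0 of the 8 passed, with 5 at an unadjusted limma p under 0.05. The list's median was -0.31 and its mean 0.41, which GH3.1 alone made positive, and camera gave an adjusted p of 0.408 in the downward direction.

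**Figure D1:**
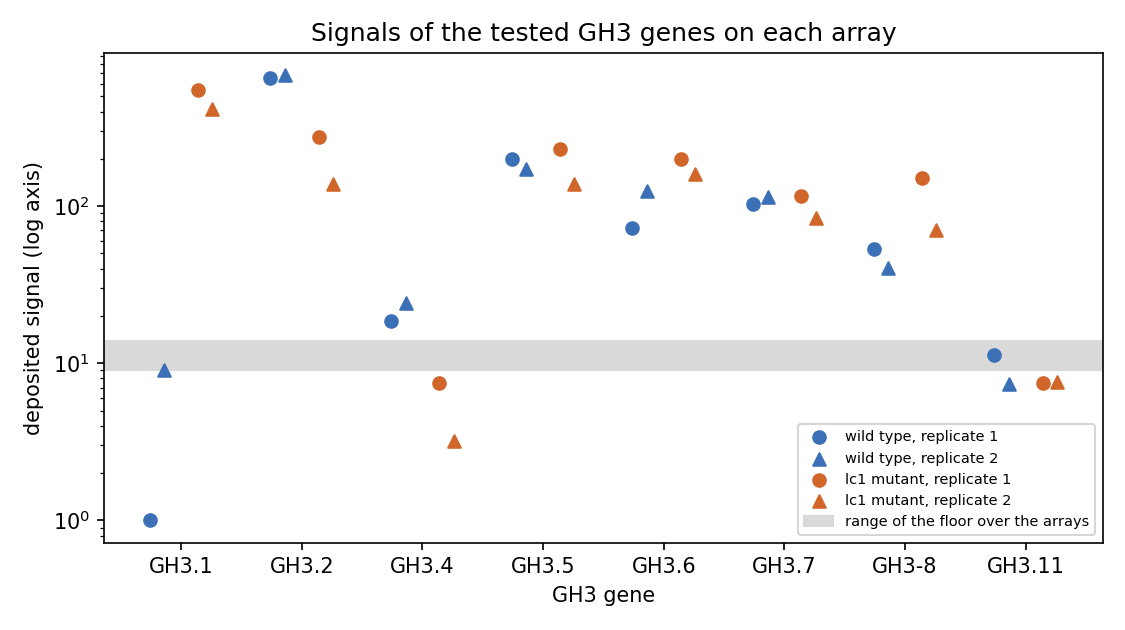
Deposited signal (log axis) of the 8 tested GH3 genes on the 2 wild-type and 2 lc1 arrays, each point 1 array, with the band marking the range of the floor over the arrays. GH3.1 lies at 1.0 and 9.0 in the wild type and at 551.8 and 418.1 in lc1, while GH3.2 lies at 651.9 and 681.0 in the wild type and at 275.6 and 138.6 in lc1.

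Of the 23 measured Aux/IAA genes, 21 lay below the median probe set and 2 above it. In all, 11 passed limma when adjusted over the list alone, each of them lower in lc1, and 0 passed over all probe sets, with 11 at an unadjusted limma p under 0.05. IAA24 measured 625.9 ± 60.9 (SD, n = 2) in the wild type and 226.0 ± 33.9 (SD, n = 2) in lc1, a log2 difference of -1.70 ± 0.25. IAA30, among the brighter members, gave -1.40 ± 0.22 with signals of 1189.5 and 1288.0 against 558.8 and 532.4. IAA20 gave -2.24 ± 0.40 with lc1 mutant 1 under the floor. IAA9 was at least 4.98-fold lower, with both lc1 arrays under the floor. Its limma adjusted p was 0.0469 without lc1 mutant 2, 0.152 without lc1 mutant 1, 0.999 without wild type 1 and 0.737 without wild type 2. The bright members that did not pass include IAA17 (-0.42 ± 0.22, with signals of 5389.7 and 6108.8 against 5703.1 and 4395.5), IAA3 (-0.25 ± 0.25), IAA5 (-0.02 ± 0.23), IAA21 (-0.04 ± 0.21) and IAA2 (-0.05 ± 0.29). Of the members above the median probe set, IAA19 gave 0.07 ± 0.26 and IAA7 was under the floor on all 4 arrays. The median of the list was -0.67 and its mean -0.81, and camera with a preset correlation of 0.01 between genes gave an adjusted p of 5.83e-16. With an estimated correlation the list did not pass (p = 0.0869, adjusted p = 0.937). The list was lower on each lc1 array taken alone against the wild-type mean, by a median of -0.78 on lc1 mutant 1 and -0.68 on lc1 mutant 2. The MADS-box genes, written as markers of panicle tissue, were lower too, with a median of -0.23 (camera adjusted p = 0.0271, and adjusted p = 0.937 with an estimated correlation), and of -0.18 and 0.03 on the 2 lc1 arrays.

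**Figure D2:**
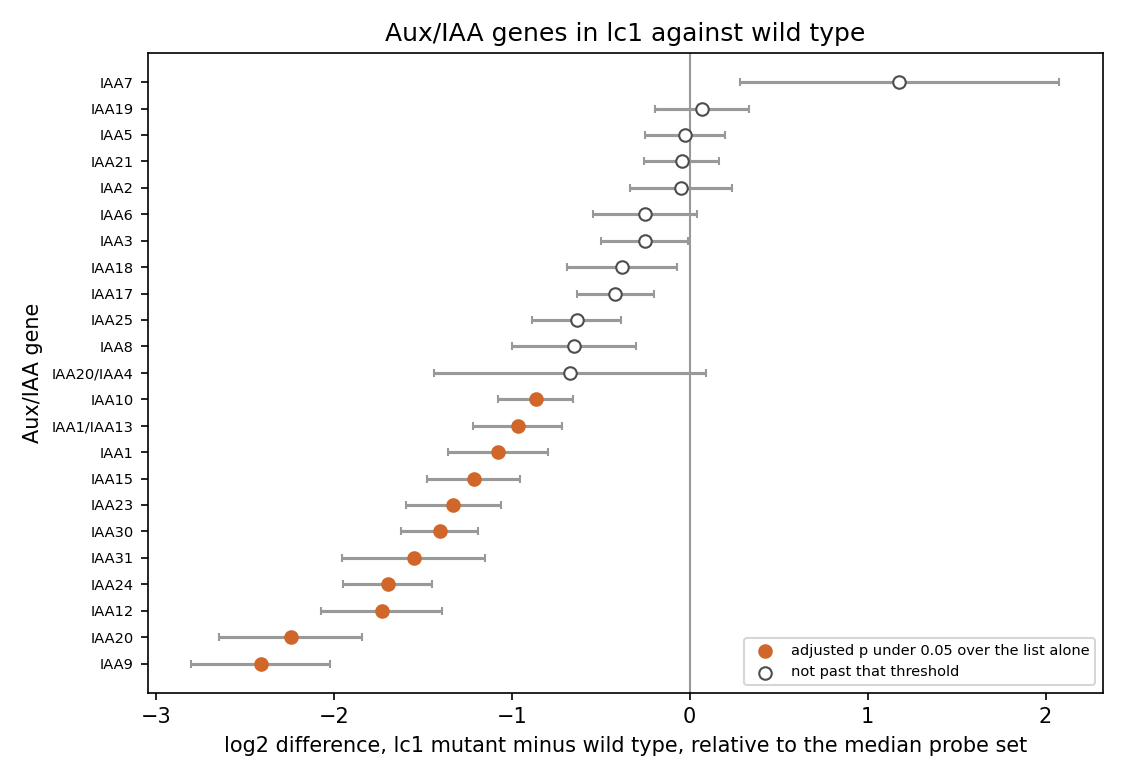
Log2 difference of lc1 minus wild type, relative to the median probe set, for the 23 measured Aux/IAA genes, with bars of 1 limma SE and 2 arrays per genotype. The 11 filled points passed when adjusted over the list alone. IAA9 is drawn at its fitted value although both its lc1 signals are under the floor, and IAA10 lies at -0.86.

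Other hormone genes showed smaller shifts. The 17 auxin response factors, transcription factors many of which bind Aux/IAA proteins, had a median of -0.30 with 12 below the median probe set (camera adjusted p = 0.0352), and adjusted p = 0.937 with an estimated correlation. Leaving out any 1 array also ended the call, with adjusted p from 0.0704 to 0.156. ARF23 gave -0.68 ± 0.22, and ARF7 lay the other way at 0.74 ± 0.27. Among the 21 brassinosteroid genes, 16 lay below and the median was -0.23 (camera adjusted p = 0.0318), and adjusted p = 0.937 with an estimated correlation. The camera adjusted p was 0.158 without wild type 2 and 0.166 without lc1 mutant 2, and without lc1 mutant 1 the median was -0.36. The only member to pass over the list alone went against that direction: CYP85A1, which catalyses late steps of brassinosteroid synthesis, measured 39.2 ± 6.15 (SD, n = 2) in the wild type and 178.6 ± 40.2 (SD, n = 2) in lc1, a log2 difference of 1.96 ± 0.32. Its limma adjusted p over all probe sets was 0.0167 without lc1 mutant 2, 0.158 without lc1 mutant 1, 0.999 without wild type 1 and 0.737 without wild type 2. CYP734A6, of a family that inactivates brassinosteroids, gave -1.55 ± 0.45. Of the 27 cytokinin genes, 18 lay below, with a median of -0.20 (camera adjusted p = 0.0352), and adjusted p = 0.937 with an estimated correlation. The median was -0.35 on lc1 mutant 1 and 0.05 on lc1 mutant 2, where 17 lay above, with each array relative to its own median. It was -0.08 without wild type 1 (camera adjusted p = 0.209), -0.07 without lc1 mutant 1 (adjusted p = 0.348) and -0.39 without lc1 mutant 2. LOGL3, of a family of enzymes that release active cytokinin, was the 1 member to pass over the list alone, at 1101.8 ± 221.0 (SD, n = 2) in the wild type and 388.9 ± 124.8 (SD, n = 2) in lc1. The 11 leaf angle and ligule genes had a median of -0.45 and a mean of -0.17 (camera adjusted p = 0.0579). CYP85A1 is also in that list, under the name DWARF, and was the only member to pass over it alone, while LG1, a regulator of the ligule and lamina joint, gave -0.64 ± 0.34.

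The jasmonate list held 24 of 30 genes above the median probe set, with a median of 0.62 and a mean of 0.70 (camera adjusted p = 0.00730). With an estimated correlation it did not pass (p = 0.487, adjusted p = 0.937), and 0 members passed limma over the list alone or over all probe sets, with 9 at an unadjusted p under 0.05. JAZ12 and JAZ5, of the family of jasmonate signalling repressors, had wild-type signals of 1061.5 and 1008.7 against 3487.8 and 1662.1 in lc1, and of 35.9 and 27.1 against 304.1 and 70.4. AOS2, an allene oxide synthase of jasmonate synthesis, had 27.3 and 31.1 against 496.6 and 41.0. The median of the list was 1.14 on lc1 mutant 1 and 0.25 on lc1 mutant 2, and without lc1 mutant 1 it was 0.12 with a camera adjusted p of 0.192, against 1.09 without lc1 mutant 2. The chitinases (11 genes, 10 above) also had unequal medians, 1.34 and 0.33, with a camera adjusted p of 0.0559 over both arrays, and Cht2 read 1280.1 and 1479.3 against 5162.4 and 2371.5.

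The other lists that camera called were close to the median probe set in size, and each had an adjusted p of 0.937 with an estimated correlation. The 23 cytosolic ribosomal protein genes had a median of 0.22 with 20 above (camera adjusted p = 0.00730), and under quantile normalization the median was 0.11 with an adjusted p of 0.204. The median was 0.13 without wild type 1 (adjusted p = 0.281) and 0.15 without lc1 mutant 1 (adjusted p = 0.109). The 22 aquaporins had a median of 0.24 with 18 above (camera adjusted p = 0.0352), and an adjusted p of 0.0540 under quantile normalization, 0.209 without wild type 1 (median 0.09), 0.0671 without lc1 mutant 1 and 0.166 without lc1 mutant 2. PIP2;5, a plasma membrane aquaporin, passed over the list alone and was at least 3.43-fold higher, with both wild-type arrays under the floor, whereas TIP4-2 gave -1.12 ± 0.25. The 28 kinesins had a median of -0.17 (camera adjusted p = 0.0352), and KIN14O gave -0.63 ± 0.26. The kinesin median was -0.30 on lc1 mutant 1 and 0.10 on lc1 mutant 2, where 16 lay above, with each array relative to its own median. It was -0.11 without wild type 1 (adjusted p = 0.191), -0.03 without lc1 mutant 1 (adjusted p = 0.412) and -0.35 without lc1 mutant 2, and the adjusted p was 0.147 under quantile normalization. The 18 MADS-box genes, written as markers of panicle tissue, had a median of -0.23 with 14 below (camera adjusted p = 0.0271) and 0 members past the threshold over the list alone (6 at an unadjusted limma p under 0.05). The median was -0.18 on lc1 mutant 1 and 0.03 on lc1 mutant 2, where 9 lay above, with each array relative to its own median. It was -0.10 without wild type 1 (adjusted p = 0.201), -0.09 without lc1 mutant 1 (adjusted p = 0.139) and -0.36 without wild type 2. MADS34 gave -1.45 ± 0.28, while OsMADS47 gave 1.06 ± 0.40. MADS15 measured 734.8 ± 14.6 (SD, n = 2) in the wild type and 262.5 ± 114.5 (SD, n = 2) in lc1 on the probe set chosen by its p, a difference of -1.78 ± 0.33, and -1.31 ± 0.28 on its brightest probe set. The former was -1.19 without lc1 mutant 1 and -2.39 without lc1 mutant 2 (limma adjusted p = 0.0122).

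Of the 42 lists tested, 9 were called, 3 higher and 6 lower, while camera with an estimated correlation and fry each called 0. Those 2 tests rest on 2 residual degrees of freedom and their power over 42 lists was not simulated, so their 0 calls alone decide no single list. The unadjusted p for Aux/IAA was 0.0869 with the estimated correlation and 0.0758 with fry. For jasmonate it was 0.487 with the estimated correlation and 0.287 with fry. The 9 calls in turn rest on the preset correlation of 0.01. At an unadjusted p under 0.05 the counts were 16 for camera, 0 with the estimated correlation and 1 for fry. On median-scaled signals limma's fry called 0, with 4 at an unadjusted p under 0.05, Aux/IAA (adjusted p = 0.180) among them. Leaving out lc1 mutant 1, camera called 5 lists, 0 higher and 5 lower, of which only the Aux/IAA and the brassinosteroid list were among the 9, and without wild type 1 it called 5, of which 3 were among the 9. Below the threshold lay the cellulose synthases (9 genes, median -0.29, camera adjusted p = 0.0559), with CESA4 and CESA7, of the secondary wall, at -1.07 ± 0.33 and -1.21 ± 0.41, and CESA5 at 0.66 ± 0.33. The abscisic acid and dehydration list had a median of -0.04 and a mean of -0.40 over 27 genes (camera adjusted p = 0.0672). Its 2 members past the threshold over the list alone were EM, a late embryogenesis abundant protein, at -2.97 ± 0.51, and LEA19, at -2.94 ± 0.59. EM gave -2.13 without lc1 mutant 1 and -3.82 without lc1 mutant 2 (limma adjusted p = 0.00725), and LEA19 read 519.2 and 166.3 against 30.8 and 64.6. The lists written as markers of other tissues gave medians of -0.23 for the MADS-box genes (18 genes, camera adjusted p = 0.0271, and adjusted p = 0.937 with an estimated correlation), 0.06 for anther and tapetum (7 genes, camera adjusted p = 0.979) and 0.02 for photosynthesis in green blade (19 genes, camera adjusted p = 0.622). The MADS-box list was selected by gene family and not by tissue, so its median does not measure panicle tissue.

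**Figure D3:**
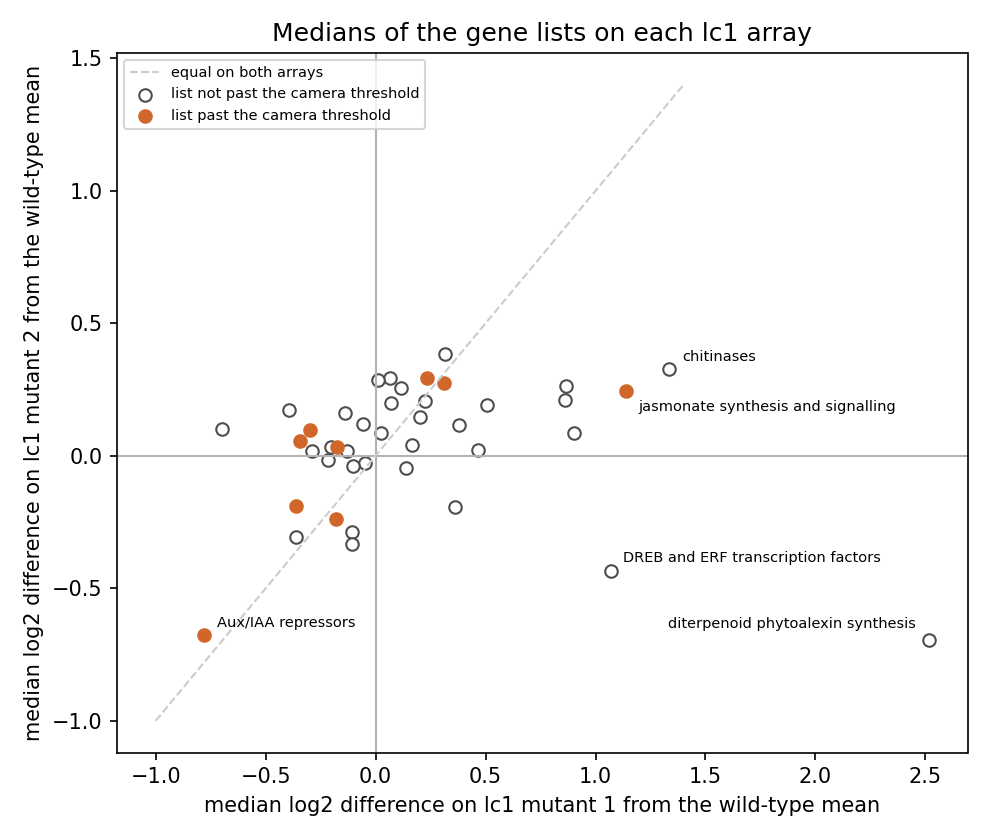
Median log2 difference of each of the 42 tested gene lists on lc1 mutant 1 (horizontal) and on lc1 mutant 2 (vertical), each against the mean of the 2 wild-type arrays. Each array was first taken relative to its own median probe set. Filled points are the 9 lists camera called; the Aux/IAA list lies at -0.78 and -0.68, the jasmonate list at 1.14 and 0.25, and the diterpenoid phytoalexin list at 2.52 and -0.70.

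Among single genes, LOC4347708 measured 205.6 ± 10.8 (SD, n = 2) in the wild type and 3787 ± 203.1 (SD, n = 2) in lc1, a log2 difference of 3.98 ± 0.22 with a limma adjusted p of 0.00796. The call was lost without wild type 1 (adjusted p = 0.0887), without wild type 2 (adjusted p = 0.0637) and with a common variance prior (adjusted p = 0.620). The 10 named genes that were higher in lc1 with the smallest p did not pass, with limma adjusted p from 0.186 to 0.365. BURP16, a BURP domain protein, had the smallest, with signals of 7.1 and 17.6 in the wild type, of which the first is under the floor, and of 322.2 and 189.8 in lc1. CIPK14, a kinase of calcium signalling, gave 1.54 ± 0.26, PPDK2 2.30 ± 0.38 and the glutaredoxin GRXC10 1.70 ± 0.30. RAA1 gave 2.17 ± 0.39, and ASMT3 gave 2.21 ± 0.40 with lc1 signals of 1822.5 and 803.0. APR1 read 742.3 ± 91.4 (SD, n = 2) against 2015 ± 412.6 (SD, n = 2). GH3.1, CYP85A1 and PIP2;5 make up the 10. Without lc1 mutant 2 each of them but PIP2;5 (adjusted p = 0.0947) passed limma, with adjusted p from 0.00506 for ASMT3 to 0.0491 for PPDK2. Without any other array none of the 10 passed except GH3.1 without wild type 2 (adjusted p = 0.0175). Under median scaling BURP16 passed limma too (adjusted p = 0.0191). Without lc1 mutant 2 the median probe set lay 0.37 log2 units higher in lc1, and limma tested against 0 with that shift kept.

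The 10 named genes that were lower with the smallest p did not pass either, with limma adjusted p from 0.341 to 0.480. They included IAA24, IAA9, IAA30 and IAA20 of the Aux/IAA family, EM, LOGL3, GH3.2 and MADS15. HSP18.1, a small heat shock protein, gave -2.06 ± 0.30 on the probe set with the smallest p and -1.04 ± 0.34 on its brightest one. MIF4 measured 122.4 ± 7.85 (SD, n = 2) in the wild type and 37.6 ± 3.61 (SD, n = 2) in lc1. Without lc1 mutant 2, EM (limma adjusted p = 0.00725), MADS15 (0.0122), HSP18.1 (0.0333), MIF4 (0.0342) and IAA9 (0.0469) passed, and none of the 10 passed without any other array.

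Over all probe sets, limma on the signals as deposited called 1 higher and 0 lower at an adjusted p under 0.05, with 2281 higher and 483 lower at an unadjusted p under 0.05. Median scaling called 16 higher and 4 lower (1941 and 956 unadjusted), and quantile normalization called 4 higher and 0 lower (1342 and 1303 unadjusted). Without lc1 mutant 2 the median probe set lay 0.37 log2 units higher in lc1, against 0.10 without lc1 mutant 1, 0.25 without wild type 2 and 0.17 without wild type 1. Limma tested against 0 with that shift kept, so calls higher without lc1 mutant 2 also hold the higher level of lc1 mutant 1. A gene-by-gene linear model without moderation, run in place of the mixed model the series names, called 0 in either direction, with 1675 higher and 513 lower at an unadjusted p under 0.05.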

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

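Of the tests in this part, the count over the other RPTR probe sets was chosen after the result was seen, and the test of the neighbours of GH3.1 before.

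A probe set with the prefix RPTR, which the annotation ties to no rice gene, gave signals of 19.0 and 3.8 in the wild type and of 3294.3 and 2120.8 in lc1, at least 151-fold higher when wild type 2 is raised to its floor. It lies outside the comparison of genes, and it stood out as a signal in lc1 far above that in the wild type. Its limma p was 6.37e-06 and its adjusted p 0.109. The adjusted p was 0.00849 under median scaling and 0.0245 under quantile normalization, and between 0.00506 and 0.0315 when any 1 array was left out. It was 0.0945 with the filter at the 60th percentile, 0.328 without a filter and 0.620 with a common variance prior, which do not pass. Its identifier carries a sequence accession, and the annotation used here does not say what that sequence is.

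This signal and that of GH3.1 were both low on both wild-type arrays and bright on both lc1 arrays. A general rise of the RPTR probe sets to a like level is argued against, since the highest signal among the other 63 was 49.5. Of these, 1 was at least 2-fold higher with the wild-type signals raised to the floor and lay above the floor on both lc1 arrays. That count cannot see small rises among probe sets under the floor. A candidate explanation is that lc1 carries an inserted sequence which the RPTR probe set detects and which raises the genes around GH3.1. The 20 measured neighbours of GH3.1, 10 on each side, had a median of 0.16 with a bootstrap SE of 0.11, and 8.94% of 16049 such windows along the genome had a median as high, so that the test leaves this open. Of these neighbours 1, LOC4325860 at 0.98 and 8 measured genes away, had an unadjusted limma p under 0.05. Their differences ran from -0.56 to 1.59. The measured genes next to GH3.1 on either side lay at 0.19 and 0.07, and the next beyond them at -0.51 and 0.65. A median over 20 genes can hardly show a rise of only the nearest few. An insertion that acts on GH3.1 alone was not tested.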

How the results depend on the processing

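The crossed replicate block and fry on median-scaled signals were chosen after the data were seen, and the other settings before. As deposited, limma called 1 probe set higher and 0 lower. The count higher was 4 under quantile normalization, 16 under median scaling (4 lower), 2 with a pseudocount, 0 with a common variance prior and 0 with the gene-by-gene model, for which 1906 and 1675 were higher at an unadjusted p under 0.05, and the cause was not tested. Without 1 array the count ran from 2 to 819 higher and from 0 to 80 lower: 819 and 80 without lc1 mutant 2, 7 and 6 without lc1 mutant 1, 3 and 0 without wild type 2 and 2 and 0 without wild type 1. These fits kept the shift of the median probe set, which was 0.37 log2 units without lc1 mutant 2 and 0.10 without lc1 mutant 1. With no test, 1596 were at least 2-fold higher and 1006 lower without overlap of the genotypes, 2602 in all. The highest of the other splits of the arrays gave 1539. On these signals, which keep the shift of the median probe set, 43.1% of probe sets did not overlap at any size, against 33.3% by chance. After median scaling the share was 40.1% by genotype and 35.7% in the crossed split, which is not by genotype. With 4 arrays the splits are too few for a share under 0.05. Same-numbered arrays did not deviate together (correlation across tested probe sets -0.04, and -0.19 over the brightest), so the numbers were not taken as pairs. The replicate block called 43 higher and 3 lower and 5 lists, and a crossed replicate block 43 higher and 7 lower and 15 lists. GH3.1 passed under median scaling (log2 7.10, limma adjusted p 0.0336), with the replicate block (7.10, adjusted p 2.49e-04) and crossed (7.10, adjusted p 0.0242), without wild type 2 (adjusted p 0.0175) and without lc1 mutant 2 (adjusted p 0.0197). It did not pass under quantile normalization (adjusted p 0.0832), with a pseudocount (0.0891), a common prior (0.620), no filter (0.510) or the filter at the 60th percentile (0.183), without wild type 1 (0.0657) or without lc1 mutant 1 (0.103). Its fitted log2 values, which ran from 5.57 without wild type 1 to 8.66 without wild type 2, do not measure its size, since both wild-type signals are under the floor and only the bound of 39.8-fold holds. Camera called 9 lists, 5 without the filter, 5 to 13 without 1 array, 0 with an estimated correlation and 0 with fry, and of the 4 lists testable as first written it called 3, 1 without the filter, 1 at the 60th percentile, 0 with an estimated correlation and 0 with fry. The Aux/IAA list kept its median of -0.67 and lost its call with an estimated correlation (adjusted p 0.937) and with fry (-0.67, adjusted p 0.813 on deposited signals, which keep the shift of the median probe set, and 0.180 on median-scaled ones), and passed in every other setting. The list diterpenoid phytoalexin synthesis ran from -0.82 without lc1 mutant 1 to 2.47 without lc1 mutant 2, each past the threshold in opposite directions. Of 613 values of the 41 lists other than Aux/IAA, 481 kept direction and side of the threshold, 54 lost the call, 33 gained it, 44 changed sign without a call and 1 changed sign with one, that of the diterpenoid list without lc1 mutant 1. Of 321 values of single genes, 290 kept both, 3 lost the call and 28 gained it. BURP16 passed under median scaling (4.25, limma adjusted p 0.0191), with the replicate block (0.00243) and crossed (0.0179), ASMT3 with these 2 blocks (2.21, adjusted p 0.0343 and 0.0366) and EM with the crossed one (-2.97, adjusted p 0.0485). Genes under the floor in a genotype have only a bound there.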

Other observations

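The tests in this part chosen after the result was seen were quantile normalization, single lc1 arrays and the other GH3 genes; those of brightness and RNA quality were chosen before.

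Genes of diterpenoid phytoalexin synthesis, the antimicrobial compounds of rice, differed between the lc1 arrays more than between the genotypes. The median of the 15 genes was 2.52 on lc1 mutant 1, with 13 above the median probe set, and -0.70 on lc1 mutant 2, with 2 above. KSL10, a diterpene synthase, read 153.4 and 36.9 in the wild type and 1722.9 and 40.8 in lc1. CYP76M7 (2.84 ± 0.62) and CYP71Z6 (-1.24 ± 0.26) passed limma when adjusted over the list alone, in opposite directions, and 0 passed over all probe sets (camera adjusted p of the list 0.978). Cold and drought regulators of the DREB and ERF list also had medians of opposite sign, 1.07 and -0.43, over 6 genes (camera adjusted p = 0.622), and DREB1B read 52.8 and 198.6 against 456.7 and 8.3.

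Most groups had smaller medians. NAC factors had medians of 0.90 on lc1 mutant 1 and 0.09 on lc1 mutant 2, and NAC071 passed over the list alone at 1.01 ± 0.30. WRKY62 and WRKY76 passed over the WRKY list alone, at 2.15 ± 0.49 and 2.51 ± 0.57, in a list whose camera adjusted p was 0.0788. The 7 clock genes had medians of -0.70 and 0.10 (camera adjusted p = 0.0619), and the bright member GI read 4659.4 and 5210.4 against 4481.1 and 4995.8. Expansins, which loosen cell walls, went both ways, with a median of 0.10 and a mean of -0.06 over 20 genes: EXPB6 gave 0.79 ± 0.25 and EXPB9 gave -2.01 ± 0.64. EXPB9 was above the floor on only 1 lc1 array. In the phosphate list SPX1 gave -1.01 ± 0.24 and PHT1-8 gave 0.90 ± 0.38, and its median was -0.28 with a mean of 0.03.

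The lower Aux/IAA signals were weighed against technical sources. A shift of level even over the probe sets had been subtracted before, so the list's median could not show it. Remaining differences in the distribution of the signals between arrays are argued against, as the median was -0.74 (bootstrap SE 0.27) under quantile normalization. Brightness is too, as 0 of 10000 random lists of equal brightness had a median as low, the lowest being -0.27. A single array is argued against, narrowly, since the median on lc1 mutant 2 alone was -0.68 (bootstrap SE 0.34). In the split that follows the Gapdh ratio the median was 0.018 (bootstrap SE 0.058), so the list did not follow that ratio. That split holds 1 array of each genotype on either side, and an even effect of the ratio would cancel between the genotypes. The test therefore could not have tied the difference by genotype to RNA quality. A lower auxin response in lc1 may account for it as a hypothesis. Of 7 other measured GH3 genes, 5 lay below the median probe set. Of these, GH3.2 (-1.99 ± 0.35) and GH3.4 (at least 1.85-fold) were clearly lower. GH3.7 (-0.35 ± 0.30) and GH3.5 (-0.27 ± 0.32) differed by little more than their error or less, and GH3.11 was near the floor. GH3-8 (0.94 ± 0.43) and GH3.6 (0.69 ± 0.34) were higher. The family thus went both ways, which leaves the hypothesis open.

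The higher jasmonate signals may come largely from 1 lc1 array. On lc1 mutant 2 alone the median was 0.25, and 976 of 10000 random lists of equal brightness had one as high, against 0 on lc1 mutant 1. An even shift of level had been subtracted before here too. Remaining differences in the distribution of the signals between arrays are argued against by a median of 0.56 (bootstrap SE 0.23) under quantile normalization. The test of RNA quality was undecided: the median in the split that follows the Gapdh ratio was 0.24 (bootstrap SE 0.09) against 0.62 by genotype, near its bound. That split holds 1 array of each genotype on either side, so an effect that follows the ratio evenly would cancel between the genotypes. It also carries the gap between the 2 lc1 arrays. A difference of genotype stays open and untested beyond this.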
